A study of Homo sapiens with 2 samples.

How the data were processed

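RNA was sequenced from EpCAM-positive cells of a head and neck squamous cell carcinoma xenograft grown in immunodeficient mice, dissociated and sorted by flow cytometry on CD276 and EpCAM, per the labels' protocols. Each of the 2 groups, CD276-high and CD276-low, holds 1 library. The sample titles name both populations as EpCAM-positive, as do the table's column names, while the wording of the sorting protocol describes a split by EpCAM; the titles were followed. Libraries were made with a KAPA RNA-Seq kit from column-purified RNA, per the labels' protocols, and whether counting used strand is not given in the sources used here. TopHat, Cufflinks and the human build hg18 are named per the submitters' processing notes, without versions. No coordinates are given because no reference of that build was used here, and how reads of mouse origin were treated is not given in the sources used here.

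The deposited values are a normalised signal per gene, and how the authors scaled them is not given in the sources used here. In each library 100% of values were whole multiples (tolerance 0.05 reads) of a single step, as for read counts divided by 1 factor per library, so whole reads were recovered. The deposited scaling had a ratio of 1.65 between the libraries, and library sizes multiplied by edgeR's TMM factors on the recovered reads gave 1.65. The authors' deposited table also holds a signed fold change, p-values and adjusted p-values for CD276-high against CD276-low, per the file headers. With 1 library per group such p-values need an assumed spread. An edgeR exact test on the recovered reads with an assumed dispersion of 0.1 gave p-values with a median distance of 0.0065 from the deposited ones and a 95th percentile of 0.0375. It called 821 genes at an adjusted p under 0.05, 344 higher and 477 lower, against 1255 in the authors' deposited table, and the method behind the deposited p-values is not given in the sources used here.

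The main measure was the log2 ratio of normalised reads, CD276-high over CD276-low, with a pseudocount of 1, over 16018 genes at 1 or more in at least 1 library. On this scale the differences of low genes are understated. The design set before the data were examined assumed FPKM-like values, and the same measure was used on the normalised reads. Genes were called higher or lower by size alone, at 2-fold or more, because 1 library per group allows no test. Folds printed for single genes are ratios without a pseudocount, with an exact 95% Clopper-Pearson interval of the share of reads turned into a ratio. A gene at 0 in a library was set against a floor of 3 reads, which is 0.109 normalised reads in the CD276-high and 0.179 in the CD276-low library. Intervals and floors cover counting error only, since 1 library per group shows no spread between sorts or tumours. Reads without molecular identifiers are not independent molecules, so the intervals may be too narrow even for counting error.

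The named genes follow a rule set before the data were examined. It took CD276 and EPCAM, the 12 largest positive and 12 largest negative differences among genes with a mean of 5 or more, up to 4 members of each of 32 gene lists by size of difference with its 2 most abundant members, and the 10 most abundant genes. Uncharacterised, small RNA and pseudogene entries were left out of the largest differences. Some genes that the rule names are not reported here. Genes outside the rule are the overlapping or related partners given beside an uncertain gene and those described as chosen afterwards. Each list with 5 or more measured members was compared by its median with 10000 random lists of the same size, matched in 20 bins of mean level, and a percentile under 2.5 or over 97.5 was taken as apart. This describes these libraries and is no test across replicates. Listed symbols were read as deposited, 25 rows whose symbols had been converted to dates were kept in all totals but not named, and XIST and Y-linked genes were left out of all gene tables.

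Alternatives covered the pseudocount (0.1 and 5), median centring, upper quartile scaling, quantile normalization, the filter on low values, the fold limit (1.5 and 4), the authors' deposited calls, list means and 10 bins. Added after the data were examined were an edgeR exact test with an assumed coefficient of variation of 0.2 and of 0.4, counts without pseudogenes, readthrough and antisense genes, pooling of BMI1 with COMMD3-BMI1, the cancer stem cell list without BMI1 and without members of the basal and EMT lists, and matching of lists on transcript length or GC content from GENCODE 29 transcripts, in 10 bins of mean level by 5 bins of the property. Of the tested genes, 96.0% had a transcript length by symbol or older symbol.

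The steps were tested on simulated libraries drawn for the 20028 listed genes at the real depths, with 200 genes changed. Reads were drawn as Poisson counts from the pooled means, without spread between libraries beyond counting error. The counts that follow therefore test the steps and give no error rate for the real libraries. All 50 genes 4-fold higher and all 50 genes 4-fold lower passed the 2-fold limit, as did 48 of 50 genes with a true log2 difference of 1.3 and 49 of 50 with -1.3, and 0 of 15405 unchanged genes passed it. A list of 20 genes changed 4-fold stood at percentile 100, and 15 of 200 unchanged lists stood apart. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16.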

Results

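Gene expression was measured by RNA-seq in tumour cells sorted from 1 patient-derived xenograft of a head and neck squamous cell carcinoma, a human tumour carried in immunodeficient mice. Cells positive for EpCAM, an epithelial adhesion molecule, were divided by their surface level of CD276 (B7-H3), an immune checkpoint ligand, into a CD276-high and a CD276-low population, with 1 library each. The deposited table listed 20028 genes as normalised reads. The recovered library totals were 24387152 reads in the CD276-high and 16956968 reads in the CD276-low library, and 1 read was worth 0.0362 and 0.0598 normalised reads. There were no biological replicates, so every difference describes these 2 libraries, and brackets give 95% intervals of a fold that cover counting error only.

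The comparison asked how EpCAM-positive tumour cells with high surface CD276 differ in expression from those with low CD276. The CD276-high library had lower levels of keratinocyte differentiation genes, with KRT13 at 2572 against 10635 normalised reads and SPRR3 at 292 against 3717. It had higher levels of basal keratinocyte genes, with LAMB3 at 658 against 184 and COL17A1 at 126 against 29.9. Cell cycle genes were also higher, with PLK1 at 101 against 41.1, while genes of epithelial junctions were lower, with PPL at 321 against 1285. Of 16018 genes at 1 normalised read or more in at least 1 library, 959 were at least 2-fold higher and 1155 at least 2-fold lower in the CD276-high library on the log2 scale with a pseudocount of 1.

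The sorted antigen followed the labels. CD276 stood at 103.5 normalised reads in the CD276-high and 37.2 in the CD276-low library, 2.78-fold higher (2.55 to 3.04), a log2 difference of 1.45. In the authors' deposited table CD276 had a fold change of 2.78, p = 0.0257 and an adjusted p of 0.214. EPCAM, positive in both gates, stood at 101.6 and 88.3, 1.15-fold higher in the CD276-high library (1.08 to 1.23). Across the 11877 genes with a mean of 5 or more, the median log2 difference was 0.0021. A value near 0 follows from the scaling, which matched edgeR's TMM and so brings most genes near no difference.

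Of 49 measured members of the keratinocyte differentiation list, 39 were at least 2-fold lower in the CD276-high library, 10 passed neither limit and 0 were 2-fold higher. The median log2 difference was -1.93, at percentile 0 among 10000 random lists matched on mean level. KRT78, a keratin of the upper epithelial layers, was 24.3-fold lower (19.7 to 30.2), and MAL, a membrane traffic protein of stratified mucosa, was 18.6-fold lower (15.4 to 22.7). TGM3, a transglutaminase that crosslinks the cornified envelope, was 16.6-fold lower (12.9 to 21.8), and SPRR3, an envelope precursor of oral mucosa, 12.7-fold lower (12.4 to 13.0). KRT13, the keratin of non-cornifying mucosa, was 4.13-fold lower (4.10 to 4.17). S100A9, a calcium-binding protein and the most abundant member, stood at 8444 against 17691 normalised reads, 2.10-fold lower (2.08 to 2.11), although with quantile normalization its log2 difference shrank to -0.36. The authors' deposited table gave 26 members of the list an adjusted p under 0.05, each lower in the CD276-high library.

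Of 17 measured basal keratinocyte genes, 9 were at least 2-fold higher, 8 passed neither limit and 0 were 2-fold lower. Their median log2 difference was 1.06, at percentile 100. COL17A1, a hemidesmosomal collagen, was 4.20-fold higher (3.82 to 4.62). The laminin chains LAMB3 and LAMA3, components of the epithelial basement membrane, were 3.58-fold (3.45 to 3.72) and 2.72-fold higher (2.55 to 2.90). CAV1, the caveolar coat protein, was 2.72-fold higher (2.47 to 2.999). The abundant basal keratins differed less, with KRT5 at 3017 against 2317 normalised reads and KRT15 at 2844 against 2841. In the authors' deposited table, 1 member of this list had an adjusted p under 0.05.

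**Figure D1:**
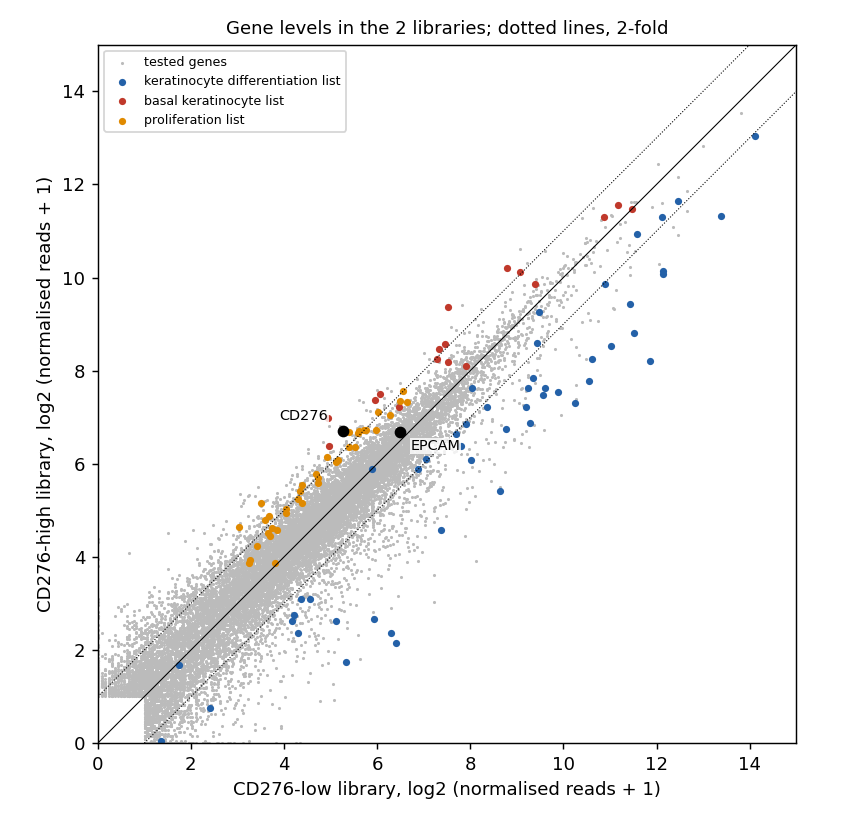
Levels of the tested genes in the CD276-low (horizontal axis) and CD276-high library (vertical axis), each as log2 of normalised reads plus 1, with 1 point per gene, the solid line at equality and the dotted lines at 2-fold. Keratinocyte differentiation genes lie mostly below the lower line, 9 of 17 basal keratinocyte and 13 of 37 proliferation genes lie above the upper line, CD276 lies above that line and EPCAM near the line of equality.

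All 22 epithelial junction genes were on the lower side in the CD276-high library and 7 were at least 2-fold lower, with a median log2 difference of -0.68 at percentile 0. PPL, the desmosomal linker periplakin, was 4.003-fold lower (3.91 to 4.10). TJP3, a tight junction scaffold, was 4.06-fold lower (3.70 to 4.45), CLDN7, a claudin, 3.13-fold lower (2.97 to 3.28), and OCLN, the tight junction protein occludin, 2.87-fold lower (2.53 to 3.26). CLDN4 and JUP, the most abundant members, were 1.96-fold and 1.64-fold lower.

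Of 26 measured genes of mesenchymal transition and partial EMT, 9 were at least 2-fold higher and 2 at least 2-fold lower, with a median log2 difference of 0.63 at percentile 100. The collagenase MMP1 was 7.32-fold higher (5.51 to 9.91), the stromelysin MMP10 7.20-fold higher (5.30 to 9.99) and TNC, the matrix protein tenascin C, 3.03-fold higher (2.92 to 3.14). Against this direction, the intermediate filament VIM was 4.97-fold lower (4.56 to 5.41) and the transcription factor ZEB2 was 14.8-fold lower (10.7 to 20.95). Leukocyte genes, described with the other cell types, were lower in the same library.

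Of 17 measured cancer stem cell associated genes, 6 were at least 2-fold higher and 2 at least 2-fold lower, with a median log2 difference of 0.57 at percentile 100. NGFR, a neurotrophin receptor of basal cells, was 4.50-fold higher (3.74 to 5.45), and SNAI2, a repressor of epithelial genes, 3.14-fold higher (2.88 to 3.43). ALDH1A3, a retinaldehyde dehydrogenase, was 3.66-fold lower (3.53 to 3.79). CD44, a hyaluronan receptor, stood at 611 against 411 normalised reads. BMI1, a Polycomb protein, was listed at 21.9 against 1.85 normalised reads, 11.8-fold higher (8.25 to 17.6), but it overlaps the readthrough gene COMMD3-BMI1, listed at 23.2 against 39.1. The pooled reads of both stood at 45.1 against 41.0, 1.10-fold higher (1.002 to 1.21), so the BMI1 difference is uncertain. The list also shares 4 members, ITGA6, ITGB1, TP63 and SNAI2, with the basal or EMT lists. Without these and BMI1, in a check added after the data were examined, 2 of 12 members were at least 2-fold higher and 2 lower, with a median log2 difference of 0.39 at percentile 99.5.

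**Figure D2:**
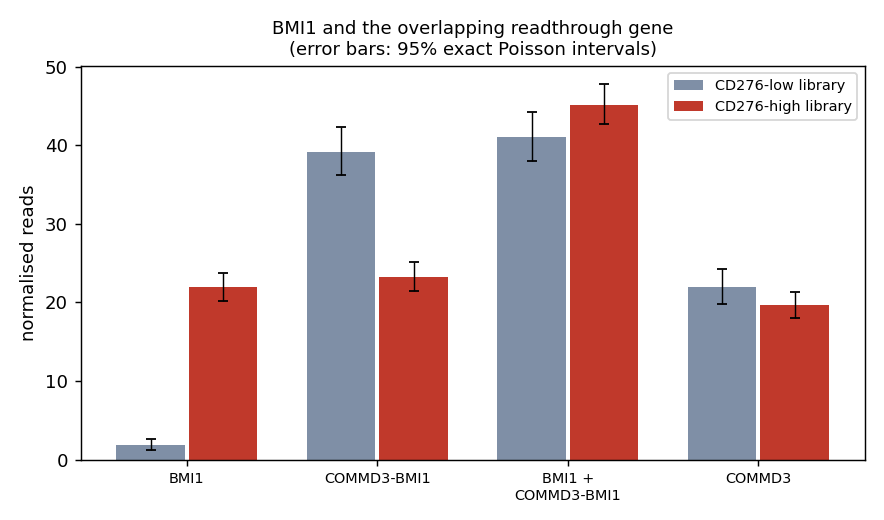
Normalised reads (vertical axis) of BMI1, the overlapping COMMD3-BMI1, their pooled reads and COMMD3 in the CD276-low and CD276-high libraries, with 95% exact Poisson intervals. BMI1 differed between the libraries, 1.85 against 21.9, while the pooled reads stood at 41.0 and 45.1.

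All 37 proliferation genes were on the higher side in the CD276-high library, 13 of them at least 2-fold, with a median log2 difference of 0.95 at percentile 100. The mitotic checkpoint kinase BUB1B was 3.35-fold higher (2.85 to 3.96), the cyclin CCNA2 3.33-fold higher (2.74 to 4.08), the mitotic kinase PLK1 2.47-fold higher (2.27 to 2.69) and the replication helicase subunit MCM3 2.38-fold higher (2.16 to 2.63). Replication-dependent histone genes went the other way, with all 17 on the lower side, 5 of them at least 2-fold, and a median log2 difference of -0.85 at percentile 0. HIST1H2AC was 3.82-fold lower (3.29 to 4.44) and HIST2H2BE 2.27-fold lower (2.08 to 2.47). Many histone genes resemble each other closely, so the value of a single member is uncertain.

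Among 29 measured immune checkpoint ligands and receptors for immune cells, a list that includes CD276 itself, 8 were at least 2-fold lower and 3 at least 2-fold higher in the CD276-high library, with a median log2 difference of -0.63 at percentile 0. HHLA2, another B7 family ligand, was 4.17-fold lower (3.18 to 5.52), C10orf54, which encodes the checkpoint protein VISTA, 3.35-fold lower (3.17 to 3.53), and the adhesion receptor CEACAM1 3.03-fold lower (2.82 to 3.25). PVRL1, which encodes nectin-1, stood at 790 against 723 normalised reads. The leukocyte marker list, described with the other cell types, was lower in the same library too (median -1.10). Whether both shifts share a source was not tested. The 20 genes of MHC class I presentation had a median log2 difference of 0.06 at percentile 80.8 and none passed 2-fold, with HLA-E at 296 against 473 and B2M at 712 against 984.

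The 36 measured interferon response genes had a median log2 difference of -0.31 at percentile 0.28, with 5 at least 2-fold lower and 2 at least 2-fold higher. The list's mean of -0.28 stood at percentile 3.43 and was no longer apart. The guanylate-binding protein GBP2 was 3.80-fold lower (3.34 to 4.33), the transcription factor IRF7 3.58-fold lower (3.23 to 3.97) and SAMD9 2.79-fold lower (2.69 to 2.91). IFITM1, an antiviral membrane protein, was 26.5-fold higher (14.3 to 55.7), at 15.8 against 0.598 normalised reads. Of its close relatives, IFITM2 was 3.13-fold lower (2.10 to 4.75), at 1.41 against 4.42, and IFITM3 2.41-fold higher (2.26 to 2.58), at 168.5 against 69.8. Reads can be split between these similar genes, so the IFITM1 value is uncertain.

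Among 30 measured cytokines and chemokines, 10 were at least 2-fold higher and 3 at least 2-fold lower, with a median log2 difference of 0.37 at percentile 99.99. CSF3, the granulocyte colony-stimulating factor, was 2.59-fold higher (2.24 to 2.99). IL36A, an epithelial cytokine, was 10.8-fold lower (9.39 to 12.5), and IL1RN, the interleukin 1 receptor antagonist, 2.76-fold lower (2.70 to 2.81). IL36G, among the most abundant members, stood at 416 against 598 normalised reads.

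Shifts upward were also seen in 3 further lists. The WNT list had 4 of 23 members at least 2-fold higher and 1 lower, with a median log2 difference of 0.41 at percentile 99.92; DKK3, a Dickkopf family protein, was 3.61-fold higher (3.23 to 4.04) and PORCN, which acylates WNT ligands, 2.28-fold lower (2.04 to 2.54). The hypoxia and glycolysis list had 3 of 31 higher and 1 lower, with a median of 0.27 at percentile 99.97. PFKFB4, a regulator of glycolysis, was 3.85-fold higher (2.92 to 5.15), and CA9, a carbonic anhydrase induced by hypoxia, 2.26-fold higher (2.09 to 2.45). The NRF2 target list had a median of 0.27 at percentile 99.95 with 0 of 24 members past 2-fold, and GCLC, a glutathione synthesis enzyme, stood at 318 against 198 normalised reads.

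For 10 pathway and stress lists the median did not stand apart from matched lists. The NOTCH list had a median log2 difference of -0.02 at percentile 43.4, with the ligand JAG2 3.12-fold higher (2.74 to 3.55), NOTCH1 2.39-fold higher (2.15 to 2.66) and HES4 3.32-fold lower (2.93 to 3.77). The EGFR list stood at -0.12 and percentile 23.6, with the receptor ERBB3 3.08-fold lower (2.87 to 3.31) and the ligand NRG1 2.55-fold higher (2.24 to 2.91). The TGF-beta and BMP list stood at -0.0012 and percentile 50.5, with ID2, an inhibitor of differentiation, 3.79-fold lower (3.08 to 4.69) and INHBA, an activin subunit, 2.44-fold higher (2.22 to 2.70). The unfolded protein and amino acid stress list stood at -0.09 and percentile 33.1, with CHAC1, which degrades glutathione, 7.24-fold lower (5.84 to 9.03). The p53 target list stood at -0.07 and percentile 32.3, and cholesterol synthesis at -0.14 and percentile 23.5. The AP-1 list stood at -0.16 and percentile 25.4, and the list of dissociation and immediate early stress at -0.17 and percentile 15.3, with FOS at 1348 against 1172 normalised reads. Nuclear-encoded oxidative phosphorylation had a median of 0.06 at percentile 89.1, and ribosomal proteins a median of 0.09 at percentile 97.4, with 0 members of either past 2-fold. The signs of the NOTCH, TGF-beta, EGFR, stress and unfolded protein medians flipped under quantile normalization. Those of NOTCH and TGF-beta, both close to 0, also flipped under upper quartile scaling. By construction that scaling adds up to about 0.07 to a log2 difference, and less for low genes because of the pseudocount. The 14 housekeeping genes had a median of 0.11 at percentile 89.1, with ACTB at 7218 against 8178 and GAPDH at 5528 against 4200 normalised reads.

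Markers of other cell types did not move alike. The tumour was carried in mice, so values of these genes may reflect tumour cells or mouse reads matched to human genes. They are therefore no measure of human stromal or immune cells. Of 16 measured leukocyte markers, 8 were at least 2-fold lower and 1 at least 2-fold higher in the CD276-high library, with a median log2 difference of -1.10 at percentile 0. SPI1, a myeloid transcription factor, stood at 0.289 against 14.4 normalised reads, 49.8-fold lower (24.9 to 116.6). CSF1R, a macrophage growth factor receptor, was 15.5-fold lower (10.4 to 24.0) and lysozyme, LYZ, 4.13-fold lower (3.63 to 4.70), while CD74, the class II invariant chain, stood at 55.9 against 54.9. Fibroblast markers had 4 of 18 members higher and 6 lower, with a median of -0.13 at percentile 17.0. COL3A1, a fibrillar collagen, was at 0 against 13.2 and so at least 121.7-fold lower against a floor of 3 reads, whereas COL6A2 was 4.78-fold higher (3.42 to 6.85). Endothelial markers had a median of -0.18 at percentile 16.3, with the clotting protein VWF 3.88-fold lower (3.49 to 4.32). Skeletal muscle markers stood at -0.54 and percentile 4.35, and adipocyte markers at -0.44 and percentile 7.56, with the fatty acid carrier FABP4 at 182 against 304. Of the erythroid markers, 1 was measured above the floor, too few for a percentile.

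**Figure D3:**
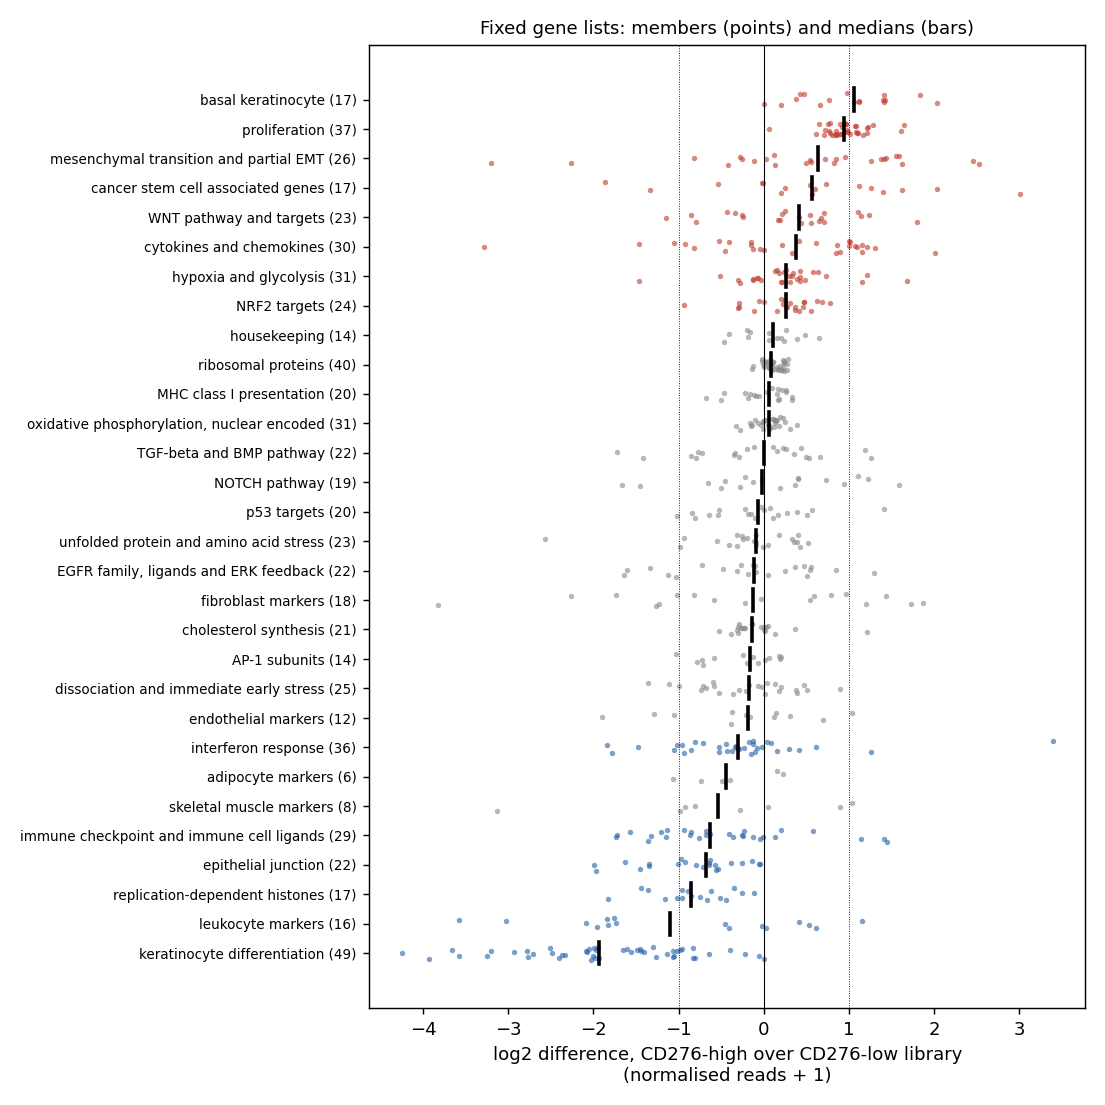
Log2 difference of the CD276-high over the CD276-low library (horizontal axis, on normalised reads plus 1) for each measured member (points) of 30 gene lists, with the list's median (bar), the number of members in brackets and dotted lines at 2-fold. Lists apart from random matched lists are coloured, with 8 shifted upward in red and 6 downward in blue; the lowest median is that of keratinocyte differentiation at -1.93 and the highest that of basal keratinocyte genes at 1.06.

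The 12 largest positive differences among genes with a mean of 5 or more included IFITM1, BMI1, MMP1 and MMP10. Membership depended on the pseudocount, and with a pseudocount of 5 the ranking shared 7 of these 12 genes and 5 of the 12 largest negative differences. NID1, a basement membrane protein, was 5.43-fold higher (4.50 to 6.59), POMC, a hormone precursor, 5.42-fold (4.27 to 6.96), STC1, a secreted glycoprotein, 4.66-fold (3.88 to 5.63) and AMOT, a cell polarity and YAP-binding protein, 7.02-fold (4.53 to 11.4). BPIFB1, a secreted airway and oral protein, was 5.65-fold higher (4.37 to 7.42), SDK2, an adhesion molecule, 4.63-fold (3.88 to 5.56) and CCDC102A 6.72-fold (4.64 to 10.04). PCNA-AS1, an antisense transcript, was at 14.5 against 0 normalised reads, at least 80.7-fold higher, but reads of PCNA on the other strand (131 against 76.1) cannot be told apart from it without strand information.

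The 12 largest negative differences included KRT78, MAL, SPRR3 and COL3A1. MUC21, a membrane mucin, was 19.99-fold lower (18.0 to 22.2), ATP13A4, a P-type transport ATPase, 19.4-fold (15.2 to 25.2) and SBK3, a kinase, 36.3-fold (24.3 to 56.6). The remaining 5 belong to families of similar sequence and are uncertain. ACTG2 was 30.3-fold and POTEF 22.9-fold lower, while ACTB was 1.13-fold lower. The ubiquitin gene UBB was 20.8-fold lower, and the heat shock gene HSPA1L was 56.2-fold lower beside 1.13-fold for HSPA1A. TBC1D3F stood at 0 against 19.4 normalised reads, at least 178-fold lower, while its family member TBC1D3H stood at 7.13 against 0.

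The 10 most abundant genes were LAMP1, S100A9, ACTB, KRT13, FTH1, KRT17, GAPDH, MTRNR2L2, KRT6A and HSPB1, and the leading 10 of each library held 6.10% of the normalised reads in the CD276-high and 8.48% in the CD276-low library. LAMP1, a lysosomal membrane protein, stood at 11764 against 14475 normalised reads, 1.23-fold lower (1.22 to 1.24). KRT17, a keratin of activated epithelium, was 1.74-fold lower. MTRNR2L2, a copy of a mitochondrial ribosomal RNA gene and so uncertain, was 2.35-fold lower (2.33 to 2.37), with a log2 difference of -0.67 under quantile normalization. In the authors' deposited table, 1255 genes had an adjusted p under 0.05, 490 of them higher and 765 lower in the CD276-high population. In the authors' deposited table, 0 proliferation and 0 replication-dependent histone genes, 2 junction genes (lower), 2 cancer stem cell associated genes (higher, NGFR and the uncertain BMI1), 2 partial EMT genes in each direction and 7 leukocyte markers (lower) had an adjusted p under 0.05.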

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

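The CD276 difference stayed above 2-fold under all 5 alternatives run, at 1.36 to 1.55 on the log2 scale. Of the 14 lists apart from matched lists, 13 stayed apart under every alternative run for them. The exception was interferon response, whose mean of -0.28 was not apart. Median centring shifts every gene alike and so could not move a list's percentile. Upper quartile scaling, with 1 factor per library, could hardly move it. Their shifts, 0.0021 and up to about 0.07, were also too small to undo the CD276 difference. Ribosomal proteins, not apart by the main measure, came out apart without a filter (0.09), with the mean (0.11), with 10 bins (0.09) and with matching on length or GC content (0.09 each), and so did skeletal muscle markers without a filter (-0.28). The cause was not tested. None of the alternatives run for them turned the direction of a list that stood apart or of a named gene past 2-fold. Among 97 named genes past 2-fold, 12 fell under the limit in at least 1 of the alternatives set before the data were examined.

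The counts of 959 higher and 1155 lower genes depend on how low genes are treated. A pseudocount of 0.1 gave 1516 higher and 1608 lower genes and one of 5 gave 219 higher and 579 lower, and a mean of 5 or more, which tests fewer genes, left 468 and 745. By construction of the limit, 1.5-fold gave 2545 and 2590 and 4-fold 50 and 217. The authors' deposited fold change put 1581 genes at 2-fold higher and 1665 at 2-fold lower, and the authors' deposited table had 490 and 765 genes at an adjusted p under 0.05. Centring, upper quartile scaling and quantile normalization kept both counts within 1.5 times, and upper quartile scaling moved the share of higher genes from 45.4% to 51.1%. Added afterwards, an edgeR exact test with an assumed coefficient of variation of 0.2 called 1081 and 1315 genes and with 0.4 only 115 and 156. These compare the libraries, not the conditions, and the calls follow the assumed spread.

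Keeping the highest of rows with a shared symbol was not run, because the only repeated symbols were date-converted and stood for different genes. No paired analysis was possible because each group holds 1 library. Counting intervals are wide for genes with few reads in a library, such as IFITM1 (10 reads in the CD276-low library) and SPI1 (8 in the CD276-high library), and the spread between separate sorts or tumours is what stays unmeasured.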

Other observations

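All gene families and tests in this part were chosen after the data were examined. Of 13 measured kallikreins, serine proteases that act in shedding of surface cells and of which 3 are also in the differentiation list, 9 were at least 2-fold lower, with a median log2 difference of -1.98 at percentile 0 and KLK6 5.81-fold lower (95% counting interval 5.51 to 6.14). Of 11 mucins, 7 were at least 2-fold lower, with a median of -2.24 at percentile 0, MUC4 6.01-fold lower (5.84 to 6.19) and MUC1 4.72-fold lower (4.61 to 4.84). The membrane serine proteases of the TMPRSS family had 7 of 14 members lower and 1 higher, with a median of -1.06 and TMPRSS11E 7.13-fold lower (6.72 to 7.57). CEACAM genes, of which CEACAM1 is also in the immune checkpoint list, had 4 of 6 lower with a median of -1.298. Serpins of clade B, with SERPINB3 and SERPINB4 also in the differentiation list, had 6 of 11 lower with a median of -1.01. Subunits of the V-ATPase, the proton pump of acid compartments, had 5 of 21 lower and a median of -0.61 at percentile 0.01.

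Basement membrane collagens were higher. Of 5 measured collagen IV chains, 4 were at least 2-fold higher, with a median log2 difference of 1.10 at percentile 99.94, COL4A2 at 1569 against 536 and COL4A1 at 1277 against 595 normalised reads. COL7A1, the anchoring fibril collagen, was 2.57-fold higher (2.47 to 2.67). Minichromosome maintenance genes, most of them in the proliferation list, had all 9 on the higher side with a median of 0.95. Of these, 2 were at least 2-fold higher. Kinesins, with KIF11 and KIF20A also in the proliferation list, had 25 of 34 on the higher side. Their median was 0.65 at percentile 100, with 6 at least 2-fold higher and 3 at least 2-fold lower. HOXA genes had 3 of 8 at least 2-fold higher, but their median of 0.46 stood at percentile 91.2, not apart. These family medians kept their signs under quantile normalization. Upper quartile scaling adds at most about 0.07 to a log2 difference, too little to turn the sign of any of them. The metallothionein MT2A was 3.42-fold higher (3.17 to 3.70), and the imprinted transcript H19 6.37-fold lower (6.09 to 6.67). Of 9 MTRNR2L genes, near-identical copies of mitochondrial ribosomal RNA and so uncertain, 8 were at least 2-fold lower.

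The first pattern weighed was lower differentiation genes with higher basal genes. Differentiation genes have shorter transcripts, with a median of 1945 bases against 4929 for the basal list, but with matching on transcript length the lists stayed at percentiles 0 and 100, and with matching on GC content at 0 and 100, which argues against either bias as the whole cause. A few genes taking most of the counts would shift all genes by a common factor. The ribosomal protein list had a median log2 difference of 0.09, with all 40 members within 2-fold. That value cannot decide the question, because the deposited scaling matched TMM, which by construction brings most genes near no difference. A common factor would also move both lists alike, whereas their medians were -1.93 (differentiation) and 1.06 (basal). What stays open, as an untested hypothesis, is that the CD276-high gate may hold more cells of a basal state. Whether it holds more cycling cells is open too and was not tested. Proliferation genes were higher (median 0.95), while all 17 measured replication-dependent histone genes were on the lower side (median -0.85). The histone values cannot decide it. Of 25 histone genes chosen, 5 were not listed, 3 lay below the floor, and the values of single members are uncertain.

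The second pattern was the lower leukocyte list in the CD276-high library, with a median log2 difference of -1.10 at percentile 0, or -1.07 with the member at 0 set to the floor, and 11 of 16 members on the lower side. Leukocytes among the cells of the CD276-low sort, which an EpCAM gate should largely exclude, are a candidate source that would lower such genes together, as seen for CSF1R (0.977 against 15.1 normalised reads), LYZ (11.97 against 49.4) and CORO1A (4.99 against 19.3) but not for HLA-DRA (45.2 against 29.3) or CD74 (55.9 against 54.9). The myeloid genes TYROBP (0 against 2.57) and AIF1 (0 against 0.777) were on the lower side too, at low levels, while for FCER1G (12 against 15 reads) the interval of the ratio, 0.207 to 1.11, included no difference. In the CD276-low library TYROBP, AIF1 and FCER1G (0.897) all lay below SPI1 (14.4) and CSF1R, so the set leaves its source open. Reads of mouse cells, which could match human genes unevenly, were not tested, and 1 of the markers, S100A4, is also in the fibroblast list. In a xenograft the leukocytes may be those of the mouse host, so leukocytes and reads of mouse cells overlap as candidates. Neither can be told apart here from expression in the tumour cells, because all would be tied to the gate, with 1 library each.

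The third pattern was BMI1, listed 11.8-fold higher in the CD276-high library. The pooled reads of BMI1 and the overlapping COMMD3-BMI1 had a log2 difference of 0.14, so an uneven assignment of shared reads may account for it. Readthrough genes in general were past 2-fold in 44.2% of 77 measured cases, against 10.4% to 27.3% in 95% of random lists matched on mean level. A change in which of the overlapping transcripts is made stays open, since transcript-level reads were not analysed here. The same caution applies to genes such as ACTG2 and POTEF, which resemble the abundant ACTB.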
